A study of Rattus norvegicus with 12 samples.

How the data were processed

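Gene expression was measured in the whole lung of 12 male Sprague-Dawley rats, with 1 Affymetrix rat genome array per lung, 3 arrays in each of 4 groups defined by surgery (sham or aortic banding) and treatment (placebo or ketotifen at 1 mg per kg per day), 9 weeks after surgery. The groups were taken from the source names in the labels. Per the labels' protocols, total RNA was labelled by a one-cycle protocol before hybridization. The values were the deposited log2 expression values per probe set, made with GCRMA in R 2.5.0 per the submitters' processing notes. GCRMA subtracts a background modelled from the base content of each probe, normalizes the arrays to each other and summarizes the probes of a probe set. Settings beyond this are not given in the sources used here. Such values flatten near background, at about 2 to 4 on the log2 scale, so that differences from an unexpressed state have an uncertain size. Scanner files were not used here, and no batch or date labels were used, so that a shared processing day could not be tested as a block.

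The table held 31099 probe sets. The 57 control probe sets were left out of all tests, and the beta-actin and GAPDH controls were used only for the signal difference between 3' and 5' probe sets. Gene symbols came from the platform annotation: 20826 of the other 31042 probe sets had 1 symbol, 436 had several and 9780 had none, and 0 symbols changed when looked up by Entrez identifier in the RefSeq gene table. No genome was used and no coordinates are given. A probe set was kept if its log2 value was at least 4 in at least 3 of the 12 arrays, which left 16536 probe sets, 13032 of them with 1 symbol, for 9788 genes. Related genes such as the hemoglobin, mast cell protease and RT1 families share probe sequence, so that values of their members are uncertain.

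Differences were tested with limma 3.58.1 in R 4.3.3, in a single fit of all 12 arrays with 4 group means (8 residual degrees of freedom, a median of 10.95 after moderation), two-sided, with eBayes and an intensity trend. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets kept. The 6 comparisons were CHF against sham with placebo, ketotifen against placebo in CHF rats, CHF against sham with ketotifen, ketotifen against placebo in sham rats, the interaction, and the average surgery effect. Standard errors are those of the moderated fit, SDs are of the 3 arrays of a group. The median difference of all kept probe sets lay between -0.04 and 0.02 in every comparison.

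Before the data were examined, 40 gene lists of lung and blood cell types, pathways and possible admixtures were fixed. Of their 683 entries 579 were on the array and 467 were kept. 36 lists had at least 5 measured genes and were tested with limma's camera, with a preset correlation between genes of 0.01, 1 probe set per gene (the one of highest mean) and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and limma's fry test were alternatives. With an estimated correlation 1 list was called, the inflammatory cytokine list, in each of 4 comparisons, and 0 in CHF against sham with placebo and in the drug comparison of sham rats. Fry kept 0 of 11 list calls in each of these last comparisons. It kept 6 of 11 for the drug in CHF rats and 7 of 13 for CHF against sham with ketotifen. For the interaction it kept 3 of 17, and for the average surgery effect 10 of 15. Counts of genes adjusted over the list alone are given beside counts over all probe sets.

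The genes named were also set by a rule made before the data were examined. For heart failure in placebo rats and for the drug in heart failure these were the 10 higher and 10 lower genes of largest difference among those called whose 3 against 3 values did not overlap, and for the other 4 comparisons 5 higher and 5 lower. Only probe sets with 1 symbol counted, with 1 probe set per gene, and symbols beginning with LOC, RGD, MGC or AABR were left out. Lists of fewer than 10 genes were filled to 10 by the smallest p, and not every gene that the rule gave is described. For the interaction the criterion of overlap does not apply, and for the average surgery effect both CHF groups had to lie apart from their sham group. Counts per list take the brighter probe set of a gene. For Mmp14 and Slc40a1, counted among the matrix and iron genes that rose, a dimmer probe set did not pass. Examples from lists came from the 4 members of smallest p, with the mast cell list described in each comparison.

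On simulated data with the variances of the real arrays, the comparison of CHF and sham placebo lungs over 16536 probe sets recovered 60% of 50 probe sets changed by 1 on the log2 scale, 88% of those changed by 2, 94% by 3 and 98% by 4, with 2 false calls, and called 0 probe sets without any change. A mast cell list of 11 genes raised by 1 was called with an adjusted p of 2.66e-05, and 0 other lists were called. Genes were drawn independently of each other there, so the simulation does not show how often lists of correlated genes are called without a change. For the same reason its few false calls do not carry over to real arrays that differ in many genes together. Among the real sham arrays, a split other than that by drug called 179 probe sets.

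Alternatives fixed in advance were no filter, a stricter filter (log2 of at least 6), quantile normalization, median centring, eBayes without the trend or with robust variance, array weights, a floor of 4, 1 probe set per gene, other thresholds, a fit with the replicate number as a block, a fit of only the 6 arrays compared, and leaving out each array in turn. Those added after seeing the data averaged CHF ketotifen arrays 1 and 3, or left out sham placebo arrays 2 and 3, the 3 arrays holding cardiomyocyte RNA, or the 3 arrays with the largest beta-actin 3' minus 5' difference. Regroupings of the arrays were all 10 splits of 6 arrays, or 100 drawn regroupings for the interaction and the average surgery effect. Figures were drawn with matplotlib 3.10.9.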

Results

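RNA from the whole lung of male Sprague-Dawley rats was measured on 12 Affymetrix rat genome arrays, in 4 groups of 3. Left heart failure, called CHF here as in the labels, had been produced by a band around the ascending aorta of juvenile rats, which raises the load on the left heart and, through it, the pressure in the lung vessels. Sham rats were operated on without the band. In each surgical group 1 arm received ketotifen, a mast cell stabilizer and histamine receptor blocker, at 1 mg per kg per day in the drinking water, and the other arm is called placebo in the labels and untreated in the design text. Lungs were taken 9 weeks after surgery. The series asks, by its title, what mast cells do in the pulmonary hypertension that follows left heart disease. The design gives 6 comparisons: heart failure without drug, the drug in heart failure, heart failure under drug, the drug in sham rats, the interaction of surgery and drug, and the average effect of surgery. The design text gives 3 rats per arm. An array has no read depth, so the number of arrays limits the precision. Between 15809 and 16056 probe sets per array had a log2 value of at least 4.

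The lungs differed in their content of airway, blood and cardiomyocyte RNA within as well as between groups. The mean log2 expression of 9 ciliated cell genes was 5.83, 9.00 and 7.85 in sham placebo lungs 1 to 3 and between 5.31 and 6.64 in the other 9 lungs. Cardiomyocyte genes averaged 7.47 in sham placebo lung 3 and 5.71 and 8.78 in sham ketotifen lungs 1 and 2, against 2.61 to 3.00 in the other 9. The 3' minus 5' signal difference of the beta-actin control, which grows as RNA degrades, was largest in sham ketotifen lung 2 (4.52) and sham placebo lungs 2 and 3 (4.23 and 3.90), and lay between 2.90 and 3.45 elsewhere. The first principal component held 45.7% of the variance and ran from -68.0 and -50.9 in sham placebo lungs 2 and 3 to 52.8, 56.6 and 73.7 in the CHF ketotifen lungs, with CHF placebo lung 1 at 38.9. CHF ketotifen arrays 1 and 3 were closer to each other (r = 0.993 across probe sets, SD of the difference 0.26) than any other pair of arrays, whose smallest SD was 0.40. They were not identical and were kept as separate samples. With these arrays averaged into a single sample, an alternative chosen after seeing the data, the counts of called probe sets were 88 in place of 201 for the drug in heart failure, and 953 in place of 2145 for heart failure under drug.

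**Figure D1:**
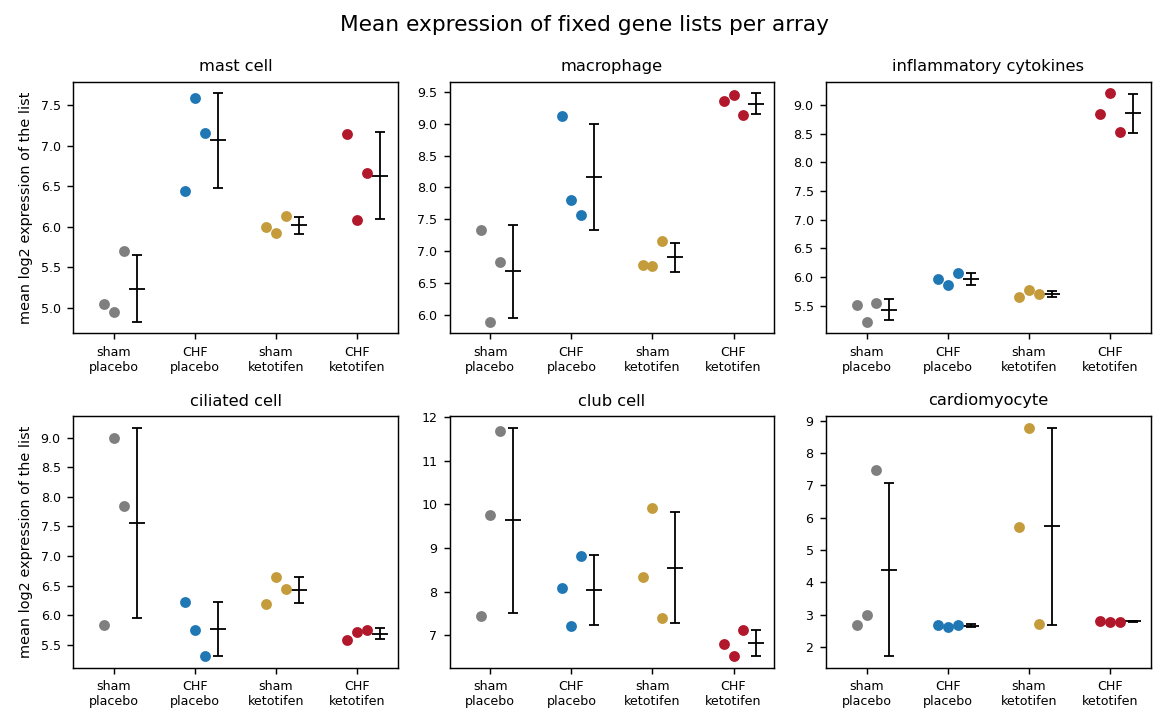
Mean log2 expression of the genes of 6 fixed lists (y axes) in each lung (points), by group (x axis), with the group mean and SD (horizontal mark and bars, n = 3). The inflammatory cytokine list lies between 8.53 and 9.21 in the CHF ketotifen lungs and at or below 6.07 in all other lungs, while the ciliated and cardiomyocyte lists are high in single sham lungs.

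In placebo rats, heart failure went with higher expression of mast cell genes and of the globin gene Hbb in the lung. Cpa3, the carboxypeptidase stored in mast cell granules, rose 16.4-fold (log2 difference 4.04 ± 0.62 SE, 3 against 3 lungs, limma adjusted p = 0.0327). Fcer1a, the alpha chain of the high-affinity IgE receptor, rose 11.3-fold (3.50 ± 0.36, adjusted p = 0.0102). The mast cell proteases Mcpt10, Mcpt1l1 and Cma1 (chymase) rose by 3.88 ± 0.47, 3.63 ± 0.51 and 3.46 ± 0.48 on the log2 scale, with adjusted p from 0.0144 to 0.0247. Hbb, which encodes beta globin, had the largest difference, 5.34 ± 0.64 (adjusted p = 0.0144), from a group mean of 8.43 (SD 1.06) to 13.77 (SD 1.31). The 4 measured red cell genes had a median difference of 4.17 and were too few for a list test. Cpa3, Fcer1a, Cma1 and Mcpt1l1 averaged below 4 in sham placebo lungs, where this array gives background signal, so the size of their folds is uncertain.

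Other genes that rose in CHF placebo lungs were Fcrla, an Fc receptor-like gene of B cells (2.93 ± 0.41), the serotonin receptor gene Htr2c (2.81 ± 0.39), the immunoglobulin gene Ighl2 (2.54 ± 0.38) and Atp8b4, of the phospholipid flippase family (2.00 ± 0.27), with adjusted p from 0.0241 to 0.0291. Cep162, which encodes a centriole and cilium protein, fell (-1.46 ± 0.19, adjusted p = 0.0221) and was the only gene with a single symbol called lower. Across 16536 probe sets limma called 24 higher and 4 lower, for 12 genes higher and 1 lower. Of the called probe sets 11 had no gene symbol or more than 1. At an unadjusted p under 0.05 there were 3326. The groups did not overlap in 23.4% of probe sets, against 10% by chance.

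Of the 11 measured mast cell genes 4 were called higher over all genes, and 7 were higher and 1 lower when adjusted over the list alone. Their median difference was 2.34 (camera adjusted p = 0.000154; adjusted p = 0.548 with an estimated correlation). It stayed between 1.80 and 2.74, with adjusted p of at most 0.0145, when each of the 6 lungs was left out in turn. None of the 16 macrophage genes passed over all genes, and 10 were higher adjusted over the list alone. Examples are Itgax (2.29 ± 0.40, adjusted p = 0.0604), Adgre1 (1.32 ± 0.29) and Gpnmb (2.07 ± 0.58). The list median was 1.37 (camera adjusted p = 2.66e-06; adjusted p = 0.548 with an estimated correlation). The 17 proliferation genes had a median of 0.79 with 0 called (camera adjusted p = 0.000154; adjusted p = 0.548 with an estimated correlation), 8 higher and 1 lower adjusted over the list alone, with Ube2c at 1.65 and Aurkb at -2.42.

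The ciliated and club cell lists were called lower by camera at the preset correlation, and not with an estimated one. None of the 9 ciliated cell genes passed over all genes and 8 were lower adjusted over the list alone, among them the axoneme genes Tekt1 (-2.71 ± 0.77), Dnai1 (-2.99 ± 0.94) and Rsph1 (-2.19 ± 0.70). The median was -1.65 (camera adjusted p = 0.000154; adjusted p = 0.548 with an estimated correlation). Of the 7 club cell genes 0 passed over all genes and 3 were lower adjusted over the list alone, with Cyp2f4 at -4.38 ± 1.13 and the secretoglobin Scgb1a1 at -0.32 (median -1.36, camera adjusted p = 0.00882; adjusted p = 0.548 with an estimated correlation). The club cell list lost its call without sham placebo lung 3 (adjusted p = 0.0869). Sham placebo lungs 2 and 3, the lungs of highest ciliated signal and larger 3' minus 5' difference, had club cell means of 9.76 and 11.69 against 7.21 to 8.81 in CHF placebo lungs.

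Smaller shifts were seen in 6 further lists, with 0 members called over all genes. The call of each was lost with an estimated correlation (adjusted p = 0.769 for smooth muscle and adjusted p = 0.548 for the others). The 18 inflammatory cytokine genes had a median of 0.25 (camera adjusted p = 0.0257), with Ccl2 at 1.70 ± 0.31 (adjusted p = 0.0636) and Socs3 at 2.13 ± 0.41. Of them 3 were higher adjusted over the list alone. Plasma cell and immunoglobulin genes had a median of 0.45 (adjusted p = 0.0275). 1 probe set of Jchain, the antibody joining chain, gave 2.36 (adjusted p = 0.0306) and a brighter one 1.75 (adjusted p = 0.115). Medians were 0.34 for MHC class II genes (adjusted p = 0.0199), 0.71 for complement (adjusted p = 0.0221), 0.22 for oxidative phosphorylation (adjusted p = 0.0033) and -0.47 for smooth muscle contractile genes (adjusted p = 0.0275). Adjusted over the list alone, 4 MHC class II, 3 plasma cell and 2 oxidative phosphorylation genes were higher, and 0 complement and smooth muscle genes passed. Calls ended for the inflammatory list without sham placebo lung 1 (adjusted p = 0.0525), sham placebo lung 2 (0.0554) or CHF placebo lung 3 (0.0866). The plasma cell list lost its call without sham placebo lung 1 (0.051) or CHF placebo lung 1 (0.0828). The complement list lost its call without sham placebo lung 2 (adjusted p = 0.0554). The smooth muscle list lost it without sham placebo lung 2 (0.778) or CHF placebo lung 3 (0.239). Its median turned to 0.26 without sham placebo lungs 2 and 3, and also without the 3 lungs of lowest RNA integrity (sham placebo 2 and 3, sham ketotifen 2), both chosen after seeing the data.

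The calls for heart failure in placebo rats rested on few lungs. Without sham placebo lung 2 limma called 0 probe sets (1982 at an unadjusted p under 0.05), without sham placebo lung 1 it called 1496, and without sham placebo lung 3 it called 10. Without CHF placebo lungs 2 or 3 it called 3 and 17. No named gene held in all 6 runs.

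**Figure D2:**
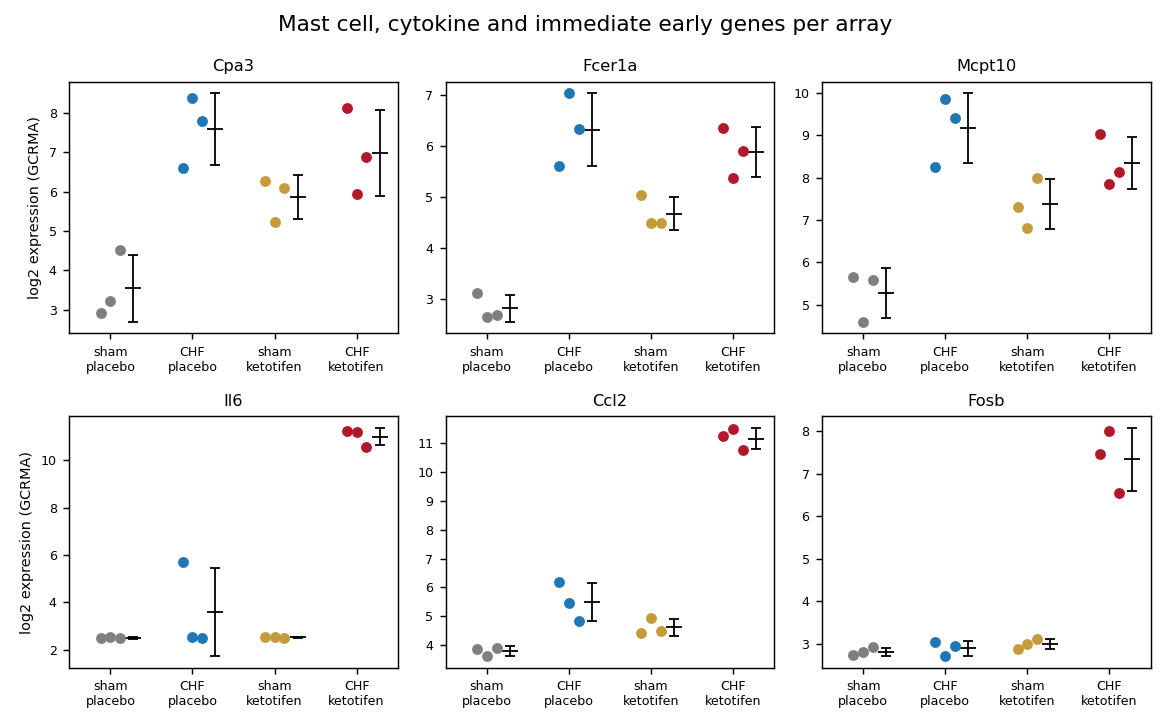
Log2 expression (y axes) of 3 mast cell genes (upper panels) and of Il6, Ccl2 and Fosb (lower panels) in each lung (points), by group (x axis), with the group mean and SD (horizontal mark and bars, n = 3). Fcer1a averages 2.82 in sham placebo and 6.32 in CHF placebo lungs, and Il6 averages 11.00 in CHF ketotifen lungs and at most 3.58 in the other groups.

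The comparison of drug and placebo within heart failure asked what ketotifen did to the diseased lung. There inflammatory genes and part of the immediate early genes were higher with the drug. Of the 11 lists called by camera 1, the inflammatory list, kept its call with an estimated correlation, and the immediate early list did not. Il6, the cytokine interleukin 6, averaged 3.58 in CHF placebo and 11.00 in CHF ketotifen lungs, a 172-fold difference (log2 7.42 ± 0.67 SE, n = 3 per group, limma adjusted p = 0.0003). The monocyte attractants Ccl7 and Ccl2 rose 55.8-fold and 50.3-fold (5.80 ± 0.20 and 5.65 ± 0.31). The neutrophil attractants Cxcl2 and Cxcl1 rose 51.4-fold and 22.0-fold (5.69 ± 0.21 and 4.46 ± 0.31). For these 4 the adjusted p lay between 2.16e-07 and 3.26e-05. Tfpi2, a protease inhibitor gene, rose 62.7-fold (5.97 ± 0.34, adjusted p = 9.37e-06). The immediate early transcription factor genes Nr4a3 and Fosb rose by 5.09 ± 0.41 and 4.45 ± 0.30, the xenobiotic-induced Cyp1a1 by 4.83 ± 0.45, and the EGF receptor ligand gene Areg by 4.68 ± 0.54 (adjusted p between 3.26e-05 and 0.00177). Apart from Cxcl1 and Ccl2 these genes averaged below 4 in CHF placebo lungs, near background, so their folds are uncertain in size. CHF placebo lung 1 alone raised the Il6 mean of its group, whose SD was 1.86.

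Genes that fell with the drug included Esm1, an endothelial proteoglycan gene (-2.78 ± 0.35, adjusted p = 0.00317), Chtf8 (-2.11 ± 0.28), C15h8orf58 (-2.05 ± 0.29) and Tmcc2 (-2.04 ± 0.25). Npr3, the natriuretic peptide clearance receptor gene, fell by 1.87 ± 0.34 (adjusted p = 0.0272) and the transcription factor gene Klf15 by 1.98 ± 0.39 (adjusted p = 0.0381; a dimmer probe set gave -2.85, adjusted p = 0.113). Further genes that fell were Trmt1l (-2.02), Tle1 (-1.75), Igip (-1.71) and Arrdc3 (-1.67), with adjusted p from 0.0248 to 0.0381. Further probe sets of Igip and Arrdc3 gave -0.57 (adjusted p = 0.175) and -1.70 (adjusted p = 0.0692). Of these 20 genes 14 were called in every run that left out 1 lung, while Npr3, Klf15, Trmt1l, Tle1, Igip and Arrdc3 lost the call in at least 1 run. Limma called 136 probe sets higher and 65 lower, for 99 and 38 genes, and 2833 had an unadjusted p under 0.05. The groups did not overlap in 25.4% of probe sets, against 10% by chance. The count was 1219 without CHF placebo lung 1, 72 and 73 without CHF placebo lungs 2 and 3, and 107, 124 and 98 without CHF ketotifen lungs 1, 2 and 3.

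The inflammatory cytokine list moved most: 13 of 18 genes rose over all genes and 14 adjusted over the list alone, with a median of 2.89 (camera adjusted p = 2.6e-21; adjusted p = 0.00162 with an estimated correlation). Of 15 immediate early genes 6 rose, and 8 rose adjusted over the list alone, among them Ier3 (1.78 ± 0.15) and Myc (1.86 ± 0.24). The median was 1.26 (adjusted p = 4.73e-10; adjusted p = 0.208 with an estimated correlation). Of 17 proliferation genes 1 rose, Ccnb1, a mitotic cyclin gene (1.74 ± 0.34, adjusted p = 0.036), and 12 rose adjusted over the list alone. A dimmer probe set of Top2a, the topoisomerase gene, also passed (1.35 ± 0.26, adjusted p = 0.036), while its brighter one did not (1.46 ± 0.32, adjusted p = 0.0597). Mki67 was at 1.85 ± 0.39. The list median was 1.46 (adjusted p = 5.75e-11; adjusted p = 0.355 with an estimated correlation). Of 5 neutrophil genes 1 rose, Il1r2, the decoy receptor for interleukin 1 (2.62 ± 0.26), and 3 rose adjusted over the list alone. S100a8 was at 2.40 and S100a9 at 1.97 (median 1.97, adjusted p = 0.00214; adjusted p = 0.355 with an estimated correlation). None of the 16 macrophage genes passed over all genes and 5 were higher adjusted over the list alone, with C1qa at 1.27 and Cd14 at 1.07 (median 1.06, adjusted p = 5.21e-06; adjusted p = 0.392 with an estimated correlation).

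The mast cell list was not called between CHF ketotifen and CHF placebo lungs. Its median was -0.47 (camera adjusted p = 0.176; adjusted p = 0.699 with an estimated correlation). In limma 0 of its 11 genes passed over all genes, where 2833 probe sets had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. That gene was Gata2, a transcription factor gene of mast cells and of other blood and endothelial cells (-1.60 ± 0.38, adjusted p = 0.0721). Tryptase Tpsb2 was at -1.14, Mcpt10 at -0.83 and chymase Cma1 at 0.60. The list was called lower without CHF placebo lung 1 (median -1.04, adjusted p = 0.0232) and without CHF ketotifen lung 1 (median -0.75, adjusted p = 0.0365).

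Further lists were called in the same comparison, none of them with an estimated correlation. MHC class II genes had a median of 0.40 (camera adjusted p = 0.00133; adjusted p = 0.355 with an estimated correlation), complement genes 0.86 (0.00165; adjusted p = 0.383 with it) and iron and heme handling genes 0.47 (0.0116; adjusted p = 0.383 with it). Hmox1, heme oxygenase, was at 1.65. Of 27 extracellular matrix genes Timp1 (1.69 ± 0.28, adjusted p = 0.0157) and Mmp2 (0.86 ± 0.16, adjusted p = 0.0331) rose. The list median was 0.20 (camera adjusted p = 0.013; adjusted p = 0.699 with an estimated correlation). In the vasoactive signalling list Npr3 fell, and Vipr1, a receptor for vasoactive intestinal peptide, was at -1.39. The list median was -0.47 (adjusted p = 0.0276; adjusted p = 0.699 with an estimated correlation). In the xenobiotic and oxidative stress list Cyp1a1 and Srxn1 (2.06 ± 0.20) rose, with a median of 0.26 (adjusted p = 0.0427; adjusted p = 0.383 with an estimated correlation). Adjusted over the list alone, 3 MHC class II, 1 complement and 3 matrix genes were higher, and 0 iron genes passed. Of the vasoactive genes 1 was higher and 3 were lower on that basis, and of the xenobiotic genes 5 and 2. The extracellular matrix call ended without CHF placebo lung 3 (adjusted p = 0.0611) or CHF ketotifen lung 1 (0.4), and the xenobiotic call without CHF placebo lung 1 (0.314) or CHF ketotifen lung 3 (0.078). The vasoactive call ended without CHF placebo lungs 2 (adjusted p = 0.114) or 3 (0.0706) and without CHF ketotifen lung 2 (0.314).

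Between CHF and sham lungs of ketotifen-treated rats many more genes differed. Il6 averaged 2.52 in sham ketotifen lungs and was 357-fold higher with heart failure (log2 8.48 ± 0.67 SE, n = 3 per group, limma adjusted p = 7.92e-05). Ccl2 was 92.3-fold and Tfpi2 73.1-fold higher. Spp1, which encodes osteopontin, rose by 7.68 ± 1.36 (adjusted p = 0.00814) and Acta1, skeletal alpha actin, by 6.16 ± 1.22 (adjusted p = 0.0128). The airway cytochrome P450 genes Cyp2a3 and Cyp2f4 fell by 4.63 ± 1.23 and 3.99 ± 1.13 (adjusted p = 0.0341 and 0.0421). Vtn, vitronectin, was at -4.40 ± 0.78, and Serpina1, alpha-1-antitrypsin, at -3.56 ± 0.71 (both lower, adjusted p = 0.00834 and 0.0135). RT1-N2, an MHC class I gene, had a difference of -3.50 ± 0.61. Only the sham ketotifen lungs were above background there, at a mean of 6.22 (SD 1.69). Il6, Tfpi2, Spp1 and Acta1 averaged below 4 in sham ketotifen lungs, and Cyp2a3, Cyp2f4, Vtn and Serpina1 in CHF ketotifen lungs. These means are near background, so the size of these differences is uncertain.

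Limma called 1052 probe sets higher and 1093 lower (746 and 636 genes), and 5149 had an unadjusted p under 0.05. The groups did not overlap in 40.1% of probe sets, against 10% by chance. Leaving out any of the 6 lungs lowered the count to between 766 (CHF ketotifen lung 2) and 1121 (sham ketotifen lung 2). Without the 3 sham lungs that held cardiomyocyte RNA, an alternative chosen after seeing the data that leaves 1 sham ketotifen lung, the count was 43. Cyp2a3, Cyp2f4 and Serpina1 lost the call in at least 1 run that left out a lung, and the other 7 named genes did not.

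Inflammatory genes again moved together, with 14 of 18 higher over all genes and a median of 2.99 (camera adjusted p = 3.64e-13; adjusted p = 0.0088 with an estimated correlation). Of the 17 proliferation genes 14 rose (median 2.32, adjusted p = 4.21e-11), among them the cell cycle kinase gene Cdk1 (3.12) and the cyclin gene Ccnb2 (2.52). Of 16 macrophage genes 12 rose (median 2.01, adjusted p = 2.51e-08), among them the receptor gene Trem2 (4.35) and the complement gene C1qa (2.35). Immediate early genes rose in 10 of 15 cases (median 1.48, adjusted p = 6.68e-06) and MHC class II genes in 7 of 9 (1.10, 2.9e-05). Sham ketotifen lungs, the reference here, had 5 probe sets of the RT1 family apart from all other lungs, 1 of them the RT1-Db1 probe set counted in this list. Complement genes rose in 7 of 11 cases (1.72, 0.000161), with C6 at 4.70, and iron and heme genes in 3 of 11 (1.29, 0.00063), with Hmox1 at 3.60. For these 6 lists the adjusted p was 0.283 with an estimated correlation. Adjusted over the list alone, 14 inflammatory, 17 proliferation, 14 macrophage, 10 immediate early, 7 MHC class II and 7 iron genes were higher, and 8 complement genes were higher and 1 lower.

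Of 21 endothelial genes 10 fell and 2 rose (median -0.86, camera adjusted p = 0.000202), with the tight junction gene Cldn5 at -1.31, the VEGF receptor gene Kdr at -1.75 and the sialomucin gene Emcn at 1.10. Of 18 vasoactive signalling genes 4 fell, Vipr1 (-1.95), Npr1 (-0.84), the serotonin transporter gene Slc6a4 (-1.64) and Ramp2 (-1.04), with a median of -0.68 (adjusted p = 0.00499). Akap5 (-2.07) and Clic5 (-1.34) were the members called among 10 alveolar type 1 genes (median -0.80, adjusted p = 0.00849). Of 27 matrix genes 5 rose and 1 fell (median 0.49, adjusted p = 0.00849), with Timp1 at 2.83, Fn1 (fibronectin) at 1.10 and Fmod at -1.41. Of the 16 oxidative phosphorylation genes 1 rose (median 0.29, adjusted p = 0.0133). Lower genes adjusted over the list alone were 11 endothelial, 8 vasoactive, 3 alveolar type 1 and 2 matrix genes. Higher on that basis were 2 endothelial, 1 vasoactive, 6 matrix and 1 oxidative phosphorylation gene. The call of each of these 5 lists was lost with an estimated correlation (adjusted p = 0.596). The cardiomyocyte list had a median of -2.81 (camera adjusted p = 0.00849; adjusted p = 0.61 with an estimated correlation) with 0 of 10 genes called. Myl7 was at -5.17 (adjusted p = 0.152), and the list had no call without sham ketotifen lung 2 (adjusted p = 0.142). Its median turned to 0.016 without the 3 sham lungs that held cardiomyocyte RNA. Calls also ended for the matrix list without CHF ketotifen lung 1 (adjusted p = 0.147) and for oxidative phosphorylation without sham ketotifen lung 3 (0.0577) or CHF ketotifen lung 2 (0.0908).

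Of the 11 mast cell genes Cma1 (2.99 ± 0.48, adjusted p = 0.00579) and Fcer1a (1.21 ± 0.36, adjusted p = 0.0493) rose and Gata2 fell (-1.90 ± 0.38, adjusted p = 0.0136) in ketotifen-treated rats with heart failure. The same counts, 2 higher and 1 lower, were found adjusted over the list alone. The list median of 0.97 was not called (camera adjusted p = 0.224; adjusted p = 0.71 with an estimated correlation).

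In sham rats the drug was compared with placebo to see its effect without heart failure. Few genes were called. Fcrla rose by 2.94 ± 0.41 SE on the log2 scale (n = 3 per group, limma adjusted p = 0.0276), and the interferon-induced gene Ifit1 by 2.47 ± 0.35 (adjusted p = 0.036). Klf10, a TGF-beta-induced transcription factor gene, rose by 0.98 ± 0.12 (adjusted p = 0.0103). Mtfr2 had a difference of -2.13 ± 0.31 (adjusted p = 0.036), and its dimmer probe set gave -0.51 (adjusted p = 0.234). The next genes by p, Atp8b4 (1.76), Plaat3 (1.21), Pola2 (1.84), Mtarc1 (-2.25) and Ehhadh (-1.15), had adjusted p of 0.0508 to 0.0512. Limma called 7 probe sets higher and 7 lower, for 4 and 2 genes. 2310 had an unadjusted p under 0.05, and 16.4% of probe sets did not overlap, against 10% by chance.

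Mast cell genes had a median of 0.70 in this comparison (camera adjusted p = 0.00661; adjusted p = 0.844 with an estimated correlation), with 0 called over all genes and 3 higher adjusted over the list alone. Fcer1a was at 1.85 ± 0.36 (adjusted p = 0.0934), Cpa3 at 2.32 and Mcpt10 at 2.08. Medians were 1.66 for cytotoxic lymphocyte and NK cell genes (camera adjusted p = 0.000509) and 0.70 for interferon response genes (0.000717), of which Ifit1 rose. They were 1.05 for T cell genes (camera adjusted p = 0.0188), 1.00 for B cell genes (0.0188), of which Fcrla rose, and 0.72 for alveolar type 1 genes (0.00661). Negative medians were found for ciliated cell genes (-1.42, camera adjusted p = 0.0174), club cell genes (-0.89, 0.0461), smooth muscle genes (-0.64, 0.0326) and xenobiotic response genes (-0.27, 0.0414). Oxidative phosphorylation genes were at 0.11 (0.0343). Higher genes adjusted over the list alone were 2 each in the interferon, T cell and B cell lists and 1 in the alveolar type 1 list. On that basis 3 xenobiotic genes were lower, and 0 passed in the other 5 lists. With an estimated correlation every list of this comparison had an adjusted p of 0.844. Several medians turned sign under alternatives chosen after seeing the data, of which the first 2 leave sham placebo lung 1 alone in its group. Without sham placebo lungs 2 and 3, the lungs of highest ciliated signal, they were 0.52 for ciliated, 0.85 for club, 0.10 for smooth muscle, 0.047 for xenobiotic, -0.011 for interferon and -0.19 for alveolar type 1 genes. Without the 3 lungs of lowest RNA integrity they were 0.35 for ciliated, 0.21 for club, 0.014 for xenobiotic, -0.19 for interferon and -0.19 for cytotoxic genes. Without the 3 lungs holding cardiomyocyte RNA the interferon median was -0.19.

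Single lungs decided most of the list calls in sham rats, and of the 11 calls the stricter filter kept 4 and fry 0. Without sham placebo lung 1 the adjusted p was 0.151 for mast cells, 0.179 for B cells and 0.095 for oxidative phosphorylation. Without sham placebo lung 2 it was 0.411 for ciliated cells, 0.778 for smooth muscle, 0.158 for club cells and for xenobiotic response, 0.0841 for T cells and oxidative phosphorylation, and 0.0848 for alveolar type 1 cells. Without sham placebo lung 3 it was 0.416 for club cells and 0.0559 for xenobiotic response. Without sham ketotifen lung 1 it was 0.109 for interferon, 0.0575 for T cells and for oxidative phosphorylation and 0.0508 for alveolar type 1 cells. Without sham ketotifen lung 2 it was 0.105 for B cells, 0.116 for oxidative phosphorylation and 0.0769 for xenobiotic response. Without sham ketotifen lung 3 it was 0.315 for smooth muscle and club cells and 0.089 for xenobiotic response. The count of called probe sets was 722 without sham placebo lung 1, 6 and 4 without sham placebo lungs 2 and 3, and 6 and 4 without sham ketotifen lungs 1 and 2. No named gene held in all 6 runs.

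The interaction asks whether the drug changed expression differently in CHF and in sham rats, and it was largest for the inflammatory genes. Il6 (7.41 ± 0.95 SE, limma adjusted p = 0.00763), Ccl7 (5.77 ± 0.29), Cxcl2 (5.55 ± 0.30), Tfpi2 (5.70 ± 0.48) and Nr4a3 (5.52 ± 0.58) had positive interactions, higher with drug in CHF than in sham rats. Fcrla (-3.70 ± 0.57, adjusted p = 0.0241), Ifit1 (-3.09 ± 0.50), Esm1 (-3.07 ± 0.50), Tmcc2 (-2.29 ± 0.36) and Chtf8 (-2.15 ± 0.39, adjusted p = 0.0496) had negative ones. These 5 lost the call in at least 1 run that left out a lung. In limma 42 probe sets were positive and 19 negative (32 and 12 genes), and 1778 had an unadjusted p under 0.05. Of 18 inflammatory genes 6 were called, all positive (median 2.26, camera adjusted p = 8.33e-17; adjusted p = 0.00379 with an estimated correlation), as were 13 when adjusted over the list alone. 4 of 15 immediate early genes were called, and 8 adjusted over the list alone, all positive (median 1.22, adjusted p = 4.35e-08; adjusted p = 0.223 with an estimated correlation). None of 11 mast cell genes was called over all genes and 4 were negative adjusted over the list alone. The median was -1.25 (camera adjusted p = 0.00062; adjusted p = 0.515 with an estimated correlation), with Cpa3 at -2.92, Mcpt10 at -2.91 and Fcer1a at -2.30 (adjusted p = 0.117). The count was 195 without sham placebo lung 1, 22 without sham placebo lung 3, and 303, 21 and 30 without CHF placebo lungs 1, 2 and 3. It was 26, 34 and 34 without sham ketotifen lungs 1, 2 and 3, and 33 and 29 without CHF ketotifen lungs 1 and 3.

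Averaged over both drug arms, the inflammatory, macrophage and proliferation lists were among those called higher in heart failure, and the ciliated and club cell lists among those called lower. With an estimated correlation only the inflammatory list of the 15 called kept its call. For the inflammatory list the drug arms differed, with a larger rise under drug than with placebo. Its interaction had a median of 2.26 (camera adjusted p = 8.33e-17, and 0.00379 with an estimated correlation). The average of that list therefore does not describe either arm alone. At the preset correlation only, interactions were also called for mast cell (median -1.25), macrophage (0.91), proliferation (1.30) and immediate early genes (1.22). The same held for MHC class II (0.60), complement (0.78), iron and heme (0.71), endothelium (-0.56) and vasoactive signalling (-0.47). Averages of these lists carry the same limit. Ccl2 rose by 4.11 ± 0.22 SE (log2, 6 CHF against 6 sham lungs, limma adjusted p = 7.01e-06), the globin gene Hbb by 3.97 ± 0.45 (adjusted p = 0.00171), the complement gene C6 by 3.67 ± 0.66, the chemokine gene Ccl9 by 3.52 ± 0.46 and the chemokine receptor gene Cxcr1 by 3.48 ± 0.59. Cyp2f4 fell by 4.18 ± 0.80, Cyp2s1 by 2.41 ± 0.57, Lypd2 by 2.36 ± 0.57, PCOLCE2 by 2.28 ± 0.44 and the cilium gene Ccdc65 by 2.27 ± 0.52. These 10 genes were called in all 12 runs that left out 1 lung. Without sham placebo lungs 2 and 3 together, which leaves 1 lung in that group, Cyp2f4 was at -2.85, Cyp2s1 at -1.28, Lypd2 at -1.40, Ccdc65 at -1.17, PCOLCE2 at -2.23, C6 at 3.62 and Cxcr1 at 2.51, with adjusted p from 0.0598 to 0.102, and Ccl2, Hbb and Ccl9 kept the call. Limma called 1827 probe sets higher and 1640 lower (1239 and 1023 genes), with 6224 at an unadjusted p under 0.05. The count was 2021 without sham placebo lung 3 and 2123 without CHF placebo lung 1. It was 297 without sham placebo lungs 2 and 3 and 60 without the 3 sham lungs holding cardiomyocyte RNA, both chosen after seeing the data.

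Of 11 mast cell genes 7 rose and 2 fell on average, with Cma1 at 3.22 ± 0.34, Cpa3 at 2.58 ± 0.44, Mcpt10 at 2.43 ± 0.33 and Fcer1a at 2.35 ± 0.25. The median was 1.57 (camera adjusted p = 0.0102; adjusted p = 0.638 with an estimated correlation). The list call ended without sham placebo lung 1 (adjusted p = 0.0523). Inflammatory genes rose in 13 of 18 cases (median 1.84, adjusted p = 8.28e-10; adjusted p = 0.0232 with an estimated correlation). Of 16 macrophage genes 13 rose (1.77, 9.51e-09), and of 17 proliferation genes 15 (1.24, 4.16e-09). Of 9 MHC class II genes 6 rose (0.71, 0.000307), of 11 iron and heme genes 5 (0.74, 0.00213), and of 11 complement genes 8 rose and 1 fell (1.31, 0.000479). For these 5 lists the adjusted p was 0.394 with an estimated correlation. Of 15 immediate early genes 8 rose (0.89, 0.000479; adjusted p = 0.451 with an estimated correlation). The counts adjusted over the list alone were 7 mast cell genes higher and 2 lower. On that basis 14 inflammatory, 14 macrophage, 16 proliferation, 7 MHC class II, 5 iron, 8 complement and 10 immediate early genes were higher, with 1 complement gene lower. Of 9 ciliated genes 4 fell (-1.18, 0.0037), of 7 club cell genes 3 (-1.57, 0.0127), and of 21 endothelial genes 10 fell and 2 rose (-0.59, 0.00167). Of the oxidative phosphorylation genes 4 of 16 rose (0.26, 0.00213). With an estimated correlation the adjusted p was 0.638 for these 4. The matrix list (6 rose and 1 fell of 27, 0.33, camera adjusted p = 0.0102) and the cardiomyocyte list (0 of 10, -2.13, camera adjusted p = 0.00761) had an adjusted p of 0.699 with an estimated correlation. The vasoactive list (5 of 18 fell, -0.44, camera adjusted p = 0.0404) had an adjusted p of 0.722 with it. In these lists 5 ciliated, 3 club cell, 12 endothelial, 7 vasoactive, 2 matrix and 0 cardiomyocyte genes were lower adjusted over the list alone. On that basis 2 endothelial, 1 vasoactive, 8 matrix and 8 oxidative phosphorylation genes were higher. The club cell median turned to 0.12 without the 3 lungs of lowest RNA integrity, an alternative chosen after seeing the data. The vasoactive call ended without sham placebo lung 1 (adjusted p = 0.115), CHF placebo lung 1 (0.0825), sham ketotifen lung 1 (0.105) or CHF ketotifen lung 2 (0.141). The matrix call ended without CHF ketotifen lung 1 (0.0673).

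Of the 28 probe sets called for heart failure in placebo rats, 24 (85.7%, exact 95% binomial interval 67.3% to 96.0%) had the same sign in ketotifen-treated rats. The interval treats probe sets as independent, which they are not, and no lung is shared between the comparisons. Random lists matched on expression level had a median share of 71.4%, and 82.1% at their 95th percentile. The median ratio of the differences, ketotifen to placebo, was 0.34, and 11 of the 28 were also called with the same sign. The 28 were picked by their placebo difference, which inflates it, so a smaller difference under drug is expected without a drug effect. The random lists were not picked in that way. None of the 28 was called with the opposite sign for the drug in heart failure by limma, where 2833 probe sets had an unadjusted p under 0.05. The opposite sign was seen for 18 (64.3%), against 64.6% in simulated data without effects, a share above chance because the CHF placebo lungs enter both comparisons. The simulated probe sets were not selected by their call as the real ones were, so these shares cannot be compared and no conclusion is drawn. The differences of these comparisons correlated across probe sets at r = 0.28 where the simulation gave -0.50, and their covariance was 0.0787 against -0.0548 simulated.

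The other 10 tested lists were called in none of the 6 comparisons. Their lowest camera adjusted p was 0.06 for heat shock genes and 0.0785 for glucocorticoid response genes (both for the drug in sham rats), 0.0792 for alveolar type 2 and surfactant genes, and 0.0924 for hypoxia response. It was 0.146 for cholesterol biosynthesis, 0.164 for fatty acid oxidation, 0.18 for circadian clock, 0.294 for mesothelium, 0.317 for lymphatic endothelium and 0.324 for alveolar fluid transport. Of the lists too small to test besides red cells, median differences for heart failure in placebo rats were -0.73 for 3 histamine handling genes, 1.38 for 2 skeletal muscle genes and 0.02 for 2 thymocyte genes.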

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

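The tests of the drug without heart failure, of more macrophages and neutrophils, of tissue handling, of blood, of MHC alleles and of the antigen presentation pathway were chosen after the result was seen. The tests of airway content and RNA integrity by covariate and of other splits of the arrays were written before their own values were seen. The airway test took the place of an earlier one, chosen after the result was seen, that left out sham placebo arrays 2 and 3 and kept the mast cell call (median 2.27, adjusted p = 7.07e-09). It was replaced because it left 1 sham placebo array. Of the tests that were run, 2 more were dropped, both chosen after the result was seen. With CHF ketotifen arrays 1 and 3 averaged the inflammatory list kept its call (median 3.11, adjusted p = 4.17e-22), and of the 4 called mast cell genes 2, Cpa3 and Fcer1a, lay outside the chymase and Mcpt family. The test of macrophages and neutrophils was changed once, because its first version used only the members called for the rise itself, and so was the bound of the antigen presentation test, because members that go both ways give a median near 0. The test of MHC alleles first used only the share of probe sets apart, written before its value was seen, and was changed because that share restates the pattern. The test of blood was also changed once: a first version set the medians of the neutrophil, T cell and B cell lists against 25% of the mast cell median. With a highest median of 0.52 it came out against blood by less than the error of those lists, and was replaced by list means with their standard errors.

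The effect of the drug differed between CHF and sham rats, by the interaction test, for 10 named genes: Il6 (log2 interaction 7.41), Ccl7 (5.77), Tfpi2 (5.70), Cxcl2 (5.55), Nr4a3 (5.52), Fcrla (-3.70), Ifit1 (-3.09), Esm1 (-3.07), Tmcc2 (-2.29) and Chtf8 (-2.15). It also differed for 17 gene lists by camera, given here by their median interaction. Positive medians were found for inflammatory cytokines (2.26), proliferation (1.30), immediate early genes (1.22), adipocyte (1.18), smooth muscle (1.01), macrophage (0.91), complement (0.78), iron and heme handling (0.71), MHC class II (0.60), xenobiotic response (0.58) and lymphoid chemokines (0.52). Some RT1 probe sets of MHC class II genes stood apart in the sham ketotifen lungs. For RT1-Bb the brighter probe set gave an interaction of 1.10 and a dimmer one -4.96. For RT1-Db1 these were 0.73 and 3.32. Negative medians were found for cytotoxic lymphocytes (-1.92), mast cells (-1.25), B cells (-1.25), alveolar type 1 (-0.95), endothelium (-0.56) and vasoactive signalling (-0.47). With an estimated correlation the inflammatory list alone kept its call (adjusted p = 0.00379), the others having adjusted p from 0.106 to 0.627. Calls of the macrophage list ended without sham placebo array 1 (adjusted p = 0.455), CHF placebo arrays 2 (0.0797) or 3 (0.078) or sham ketotifen array 2 (0.088). B cell and complement calls ended without sham placebo array 1 (0.0574 and 0.0719). Endothelial and vasoactive calls ended without CHF ketotifen array 2 (0.0582 and 0.0813), and the adipocyte call without sham placebo array 3 (0.119) or sham ketotifen array 3 (0.0778). Smooth muscle lost its call without sham placebo array 2 (0.286), CHF placebo array 3 (0.057) or sham ketotifen array 3 (0.112). For lymphoid chemokines 7 arrays ended the call: sham placebo 2 (0.128) and 3 (0.0592), CHF placebo 2 (0.0635), sham ketotifen 1 (0.0665) and 3 (0.129), and CHF ketotifen 2 (0.0582) and 3 (0.0521). Its median turned to -0.11 without sham placebo arrays 2 and 3. For iron and heme handling these were sham placebo 1 (0.109) and 3 (0.0848), CHF placebo 2 (0.0635) and 3 (0.126), sham ketotifen 2 (0.164) and 3 (0.0631), and CHF ketotifen 1 (0.0841).

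Inflammatory genes and part of the immediate early genes were higher in CHF ketotifen than in CHF placebo lungs. With an estimated correlation 1 of the 11 lists called there, the inflammatory list, kept its call, and the immediate early list did not. An effect of the drug that needs no heart failure is argued against, since the inflammatory list had a median of 0.10 in sham rats, against 2.89 in CHF rats, and its interaction was called (adjusted p = 8.33e-17). More macrophages and neutrophils cannot be told apart from a change in expression per cell. The differences of the 33 members of the inflammatory and immediate early lists averaged 2.29 ± 0.16 (SE), against 1.15 ± 0.47 for the macrophage and 1.62 ± 0.51 for the neutrophil markers, but the marker that rose most, Spp1, was at 2.66 ± 1.36. Taken alone, the inflammatory list averaged 2.90 ± 0.17, above both marker lists, and the immediate early list 1.56 ± 0.22, which is not above the neutrophil markers. The large error of Spp1 set a bound that the list mean could hardly pass, so the test itself cannot decide. An effect of tissue handling or of a shared processing day cannot be told apart from an effect of the drug in heart failure, because no label parts the day from the group: the immediate early list, which may respond to handling, had a median of 1.26 and the heat shock list -0.07. The biological explanation, an effect of the drug that appears with heart failure, stays open and was not tested apart from these.

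Mast cell genes were higher in CHF placebo than in sham placebo lungs. More blood is left open: list means rose by 0.63 ± 0.51 for neutrophils, 0.57 ± 0.33 for T cells and 0.50 ± 0.34 for B cells (SE), against 1.83 ± 0.37 for mast cells and 3.62 ± 0.71 for red cells, so that blood cannot be told apart with these errors. Different amounts of airway are argued against as the whole cause, since with the ciliated cell mean as a covariate the mast cell list mean was 1.72 ± 0.53 in place of 1.83 ± 0.37, and its median 1.90. The ciliated median went to -0.14, which follows by construction from the covariate. Airway content is thus covered only as far as the ciliated mean tracks it. The mast cell list was called in that fit at the preset correlation (adjusted p = 6.17e-06) and not with an estimated one (0.68), as without a covariate (0.548). Single genes lost their limma calls in that fit (0 probe sets called, 1405 at an unadjusted p under 0.05), with Fcer1a at 3.08 ± 0.47 (adjusted p = 0.15) in place of 3.50 ± 0.36. The median standard error grew from 0.22 to 0.28. With the beta-actin difference as a covariate the mast cell list mean was 1.74 ± 0.45 and its median 2.15. Sham placebo and CHF placebo lungs did not overlap in that difference, at 3.45 to 4.23 and 3.01 to 3.40. The adjustment thus rests on a slope drawn from lungs within groups. It argues only against a linear effect of RNA integrity as strong as that slope, and RNA integrity otherwise stays open. The mast cell list was called in that fit at the preset correlation (adjusted p = 0.00115) and not with an estimated one (0.662). Fcer1a was at 3.27 ± 0.41 (adjusted p = 0.046), and 5 probe sets were called. A larger number of mast cells, and more transcript per mast cell, stay open and were not tested.

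Some probe sets for the rat MHC, RT1, stood apart in the 3 sham ketotifen lungs. Of 27 RT1 probe sets 18.5% had all 3 sham ketotifen values above (3) or below (2) those of the other 9 arrays, against 1.86% of all 16536 probe sets (Fisher's exact test, two-sided, p = 0.000123, with probe sets that share sequence counted as independent). This share shows the pattern and not its cause. Alleles that differ between rats and alter the match to the probes are a candidate explanation that stays open, since of 5 RT1 genes with several probe sets 1, RT1-Bb, had probe sets that differed in opposite directions by over 2 standard errors each. A probe set of RT1-Db1 read 5.95, 6.37 and 5.74 in sham ketotifen lungs and 8.85 to 10.31 elsewhere, and RT1-N2 read 7.41, 6.97 and 4.29 against about 2.7. The dimmer RT1-Bb probe set read 9.35, 9.68 and 5.43 against 3.11 to 3.23 elsewhere. The CHF ketotifen lungs, given the same drug, read 3.19 to 3.23 there. A drug effect on antigen presentation in sham rats cannot be told apart from such alleles, since the MHC class II list had a median of -0.041 (camera adjusted p = 0.647) over members that went both ways, from -0.92 to 0.74. Whatever set the sham ketotifen lungs apart also enters the comparison of heart failure under drug and the interaction. Genotypes were not analysed here.

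Counts of calls were compared with those of other splits of the same arrays. With 6 arrays there are 10 splits, too few for a share under 0.05, and only values are given. The real split gave 28 calls for heart failure in placebo rats and the highest other split 1. The numbers were 201 and 0 for the drug in heart failure, 2145 and 0 for heart failure under drug, and 14 and 179 for the drug in sham rats. In each of the former 3 comparisons 1 of 10 splits, the real one, gave as many calls, and in sham rats 2 of 10 did. A split that called 179 points to a structure among the sham arrays other than the drug. The size of the mast cell median was 2.34 against a highest other of 1.55 for heart failure in placebo rats (1 of 10 as large). It was 0.47 against 1.14 for the drug in heart failure (4 of 10), and the inflammatory median was 2.89 against 1.47 (1 of 10). Of 100 regroupings of drug labels within surgery 2 gave as many calls as the 61 of the interaction, the highest other giving 82. Of 100 regroupings of surgery labels within drug arm 1 gave as many as the 3467 of the average surgery effect, the highest other giving 1497. For the average surgery effect chance assignment is argued against at a share of 0.05. These regroupings remove the surgery effect in both drug arms, so their share speaks to an effect of surgery in either arm. It does not show an effect shared by both arms, and it counts CHF ketotifen arrays 1 and 3 as separate samples. For the interaction the regroupings also remove the drug effect within heart failure, so their share speaks to a drug effect in either arm and not to the interaction alone. The 14 of them that keep the drug split of the CHF arrays, the real one included, gave 28 to 61 calls, the highest other giving 51, and are too few for a share under 0.05.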

How the results depend on the processing

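Averaging CHF ketotifen arrays 1 and 3, and leaving out sham placebo arrays 2 and 3, the 3 arrays with cardiomyocyte RNA or the 3 of lowest RNA integrity, were chosen after seeing the data. All other alternatives were planned. Where a value moved, the cause was not tested, except that fewer arrays, fewer or more probe sets and other thresholds change counts by construction. GCRMA signal near background limits the size of differences of dim genes, and the number of arrays limits the rest.

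Called probe sets are given in the order heart failure with placebo (28), drug in heart failure (201), heart failure under drug (2145), drug in sham rats (14), interaction (61) and average surgery effect (3467). Without a filter the counts were 9 for heart failure with placebo, 1156 for heart failure under drug, 36 for the interaction and 2311 for the average. With the stricter filter the drug in sham rats gave 7. Array weights gave 8291, 5576, 4275, 3747, 3169 and 7849. Their estimation stopped before convergence and gave sham placebo array 3 a weight of 35.1. With 1 probe set per gene heart failure with placebo gave 13. With only the 6 arrays compared, limma gave 0 for heart failure with placebo (2506 at an unadjusted p under 0.05), 60 for the drug in heart failure and 2 for the drug in sham rats. At an adjusted p under 0.10 the counts were 210, 597, 3722, 60, 104 and 5335. At an unadjusted p under 0.01 they were 1146, 1090, 638 and 552 for heart failure with placebo, the drug in heart failure, the drug in sham rats and the interaction. With a difference of at least 1 on the log2 scale they were 1139 for heart failure under drug and 885 for the average. Quantile normalization, median centring, a floor of 4, robust variance and no trend kept every count within 1.5 times.

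With CHF ketotifen arrays 1 and 3 averaged the counts were 88 for the drug in heart failure, 953 for heart failure under drug and 28 for the interaction, each a subset of the original calls, and the calls for heart failure with placebo went from 28 to 6, of which 100% in place of 85.7% had the same sign under drug. Without sham placebo arrays 2 and 3 limma gave 0 for heart failure with placebo (810 at an unadjusted p under 0.05), 0 for the drug in sham rats (743), 11 for the interaction and 297 for the average. Without the arrays holding cardiomyocyte RNA it gave 0 (2042), 43 for heart failure under drug, 3 for the drug in sham rats, 3 for the interaction and 60 for the average. Without the arrays of lowest RNA integrity it gave 0 (925), 984, 0 (607), 2 and 197 in the same order.

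Leaving out 1 array at a time gave 0 to 1496 calls for heart failure with placebo, 72 to 1219 for the drug in heart failure, 766 to 1121 for heart failure under drug, 4 to 722 for the drug in sham rats, 21 to 303 for the interaction and 2021 to 4299 for the average. The 0 came without sham placebo array 2 and the 1496, 722 and 4299 without sham placebo array 1. The 4 came without sham placebo array 3 and without sham ketotifen array 2. The 1219 and 303 came without CHF placebo array 1, the 72 and 21 without CHF placebo array 2, the 766 without CHF ketotifen array 2, the 1121 without sham ketotifen array 2 and the 2021 without sham placebo array 3. The repeat under drug ranged from 87.1% to 100%. The mast cell median for heart failure with placebo ranged from 1.80 to 2.74, called in 6 of 6 runs, that for the drug in heart failure from -1.04 to -0.11, called in 2 of 6 (without CHF placebo array 1 and without CHF ketotifen array 1), and the inflammatory median for the drug in heart failure from 2.35 to 3.26, called in 6 of 6.

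The same-numbered arrays of the groups showed little tendency to deviate together (5 of 18 pairs with r over 0.1, median 0.05, range -0.35 to 0.26). This gave no clear sign that the numbers pair the rats, but so few arrays per group cannot exclude it. With the replicate number as a block the counts were 27, 145, 1899, 6, 37 and 3290.

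The mast cell list with placebo, median 2.34, lost its call with an estimated correlation (adjusted p = 0.548) and with fry (0.051). Other lists lost calls too. In the order of the counts above, fry kept 0 of 11, 6 of 11, 7 of 13, 0 of 11, 3 of 17 and 10 of 15 list calls. An estimated correlation kept 0, 1, 1, 0, 1 and 1.

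Some differences turned sign. Leaving out sham placebo arrays 2 and 3, or the arrays of lowest RNA integrity, which include them, leaves 1 sham placebo array, assumed to vary like the other groups, so that calls of either direction there rest on 1 array. Without sham placebo arrays 2 and 3 these were, for heart failure with placebo, Cnn1 (0.21), Lmod1 (0.015) and the smooth muscle list (0.26). For the drug in sham rats they were Des (0.047), Cnn1 (0.53), Ager (-0.20), Hopx (-0.19), Aldh1a1 (0.21), Cyp2f4 (0.85), Tekt4 (0.69), Rsph9 (0.55), Rsph1 (0.48), Tekt1 (0.52). Its lists were those of interferon (-0.011), smooth muscle (0.10), alveolar type 1 (-0.19), club (0.85), ciliated (0.52, called in that direction at adjusted p = 0.000422) and xenobiotic genes (0.047). For the interaction they were Ccl20 (-0.60), Cxcl12 (-0.11), Cidea (-0.058) and the lymphoid chemokine list (-0.11). Without the arrays of lowest RNA integrity they were Cnn1 (0.21), Lmod1 (0.015) and the smooth muscle list (0.26) with placebo. For the drug in sham rats they were Prf1 (-0.044), Gzma (-0.32), Cnn1 (0.42), Hopx (-0.0023), Aldh1a1 (0.14), Cyp2f4 (0.21), Tekt4 (0.67), Rsph9 (0.32), Rsph1 (0.35), Tekt1 (0.39). Its lists were those of cytotoxic (-0.19), interferon (-0.19), club (0.21), ciliated (0.35, called at adjusted p = 0.00287) and xenobiotic genes (0.014). For the average they were Scgb3a1 (1.03) and the club list (0.12). Without the arrays holding cardiomyocyte RNA they were Tnnc1 (0.060) and the cardiomyocyte list (0.016) for heart failure under drug, the interferon list for the drug in sham rats (-0.19) and Scgb3a1 for the average (0.081). Without CHF placebo array 1, Il6 with placebo was -0.0044, and over all runs leaving out 1 array it reached 1.61 (without CHF placebo array 3). Of all other gene values under alternatives, 2645 of those leaving out 1 array and 4285 of the others kept direction and side of the threshold, 268 and 413 lost the call, and 92 and 194 gained it; of the list values 595 and 664 kept both, 75 and 201 lost the call, and 2 gained it.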

Other observations

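The lungs of the CHF placebo group differed among themselves in genes that were high in all CHF ketotifen lungs, as seen in genes picked after their values were known. CHF placebo lung 1 read 9.70 for skeletal alpha actin, Acta1, and 11.14 for osteopontin, Spp1, where CHF placebo lungs 2 and 3 read 6.62 and 2.84 for Acta1 and 8.16 and 6.01 for Spp1. The CHF ketotifen lungs lay between 8.51 and 9.03 for Acta1 and between 10.14 and 11.70 for Spp1. The macrophage list averaged 9.12 in CHF placebo lung 1, 7.81 and 7.56 in CHF placebo lungs 2 and 3, and 9.13 to 9.46 in CHF ketotifen lungs. The mean of the inflammatory list did not follow this order, at 5.96, 5.85 and 6.07 in CHF placebo lungs 1 to 3 and 8.53 to 9.21 in CHF ketotifen lungs. Single members could differ from the mean, and Il6 was highest in CHF placebo lung 1 among the CHF placebo lungs.

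Between CHF and sham lungs of ketotifen-treated rats, Gata2 and the chymase gene Cma1, both of the mast cell list, differed in opposite directions (-1.90 ± 0.38, limma adjusted p = 0.0136, and 2.99 ± 0.48, both from 3 against 3 lungs). For the drug in heart failure Gata2 (-1.60) was negative together with Tpsb2 (-1.14), Mcpt10 (-0.83) and Cpa3 (-0.61), and Cma1 was at 0.60. Gata2 is also expressed in endothelial and other blood cells.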
